A study of Mus musculus with 6 samples.

How the data were processed

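RNA sequencing was done on total RNA of ileum from C57BL/6J mouse pups, with 3 control libraries (phosphate-buffered saline) and 3 AVNM libraries. Per the labels, RNA was extracted with the Direct-zol miniprep kit and libraries were made with the KAPA RNA HyperPrep kit. The design text puts the mice in separate cages of different litters but does not say whether a library came from 1 pup or several, so the p-values measure the spread between libraries. Per the submitters' processing notes, reads were trimmed with Trim Galore and aligned with STAR, and the builds named are mm39 and GRCm39; versions, the counting tool, the annotation release and the strand setting are not given in the sources used here. The authors deposited a raw table whose unit is counts, whole numbers for 55359 genes, of which 31498 have at least 1 count. The authors also deposited a normalized table whose unit is signal, with 19226 genes: each value is the raw count divided by 1 constant per library (largest relative deviation 4.996e-15), and how the authors derived that constant is not given in the sources used here. The normalized table keeps genes with a total count as low as 11 and leaves out genes with a total as high as 60, so its filter is not on the total alone.

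Gene IDs were matched to symbols, transcript length and GC content through a reference annotation of the earlier build GRCm38, so no positions are given. Of the IDs, 52083 had a symbol; 0 of the table's entries name no gene; and 17487 (99.4%) of the tested genes had a symbol, a length and a GC content. Nuclear copies of mitochondrial genes carried almost the same counts as the genes themselves, such as Gm28661 with 100.01% to 100.04% of mt-Co2. The same reads were therefore probably counted for both, and the copies are not read as expressed. The mitochondrial share of counts and the removal of mitochondrial genes cover only genes whose symbols begin with mt-, not these copies.

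The raw counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (min.count 10, min.total.count 15), libraries were scaled by TMM factors, and AVNM was compared with control by edgeR's quasi-likelihood test with robust estimation, two-sided, with Benjamini-Hochberg adjustment over 17587 genes and a threshold of 0.05. The common biological coefficient of variation was 13.4%. CPM are edgeR's counts scaled to the TMM-scaled library size; log2 CPM used a prior count of 2. Standard errors of log2 fold changes come from the same model. Genes called at least 2-fold have a log2 fold change of 1 or more in size.

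The 51 gene lists, the groups, the tests and the alternatives were fixed before the data were examined. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, beside it with an estimated correlation and with fry, adjusted over the lists. For each list the genes past the edgeR threshold were also counted after adjustment over the list's members only. The rule for named genes, also fixed in advance, took the 12 largest rises and the 12 largest falls among genes that passed, with a mean log2 CPM of at least 1, a gene symbol that is not a predicted or clone name, and no overlap between groups. It added up to 4 members with the smallest p of each list that was called or held a passing gene, and a set of marker genes given whether or not they passed. The largest changes are all given, as are the markers apart from some that are not reported here, while of the list members up to 4 per list are printed and the rest are summarised as counts. Amy2a5, the Y-linked genes, Xist, Gla, Onecut2 and the genes of lists written later were chosen after their values were seen. Values of multigene families (Defa, immunoglobulin, H2, Sprr2 and replication histone genes) are uncertain because their members share sequence.

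The workflow was tested on simulated data with 17199 genes. In a single run, 48 to 50 of the tested genes were changed at each size. The workflow recovered 35.4% of genes changed 1.5-fold, 65.3% at 2-fold, 95.9% at 4-fold and 100% at 8-fold. Of 160 calls 14 were wrong (8.75%), a share above the threshold set for the adjusted p. The share of genes changed was smaller than the 8.36% called in the data. Recovery and wrong calls depend on that share, so these rates may differ in the data. Of 50 unchanged lists 0 were called, which does not show how often camera errs on the real lists. In the data, splits of the libraries that mix AVNM and control had 5 to 20 lists called. The estimated correlation within a list reached 0.947, for mitochondrially encoded genes. Alternatives fixed in advance were RLE and upper-quartile factors, library size only, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, limma-trend on the authors' normalized values, removal of mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes, the replicate number as a block, each library left out in turn, an adjusted p under 0.1, and a prior count of 0.5 for lists. Alternatives chosen after seeing the data were Xist or Fabp6 as a covariate, protein-coding genes only, a correction for GC content and length, and leaving out both controls that hold Xist. All 6 libraries were used, and the comparison was repeated over the 10 splits of the libraries into groups of 3.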

Results

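The data are RNA sequencing of ileum, the last segment of the small intestine, from C57BL/6J mouse pups taken at day 14 after birth. From day 3 to day 14 the pups received by gavage, once a day, either phosphate-buffered saline (control, n = 3 libraries) or AVNM, a cocktail of the antibiotics ampicillin, vancomycin, neomycin and metronidazole (n = 3 libraries). The single comparison, AVNM against control, asks how gene expression in the postnatal ileum differs after antibiotics that disturb the gut microbiota. The data used here hold no measure of the microbiota. A change that came through the microbiota can therefore not be told apart from a direct action of the drugs on the tissue. The control libraries held 9578280, 10955712 and 11004277 counts and the AVNM libraries 8954418, 11682607 and 13815355 counts, and 17587 genes had enough counts to be tested. On the first principal component of the 1000 most variable genes, with 53.3% of the variance, the controls lay at -18.1, -35.5 and -7.33 and the AVNM libraries at 10.5, 26.9 and 23.5, so that control 3 lay nearest to the AVNM group. Across genes, which are not independent replicates, the Pearson correlation of log2 CPM (counts scaled by library size) ranged from 0.976 to 0.983 between libraries of the same group and from 0.954 to 0.979 between groups, so the ranges overlap; the highest between groups was that of control 3 with AVNM 1. Xist, the RNA of the inactive X chromosome, stood at 1561, 1730.1 and 8.39 CPM in controls 1 to 3 and at 3.10, 1.94 and 1839 CPM in AVNM 1 to 3. The sum of the Y-linked genes Uty, Kdm5d, Eif2s3y and Ddx3y was 106, 77.0 and 309 CPM in the controls and 282, 295 and 1.71 CPM in AVNM, so controls 1 and 2 held both Xist and Y-linked RNA. Counts of Amy2a5, the amylase of pancreatic acinar cells, were 10, 423 and 459 in the controls and 339, 1 and 18 in AVNM.

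**Figure D1:**
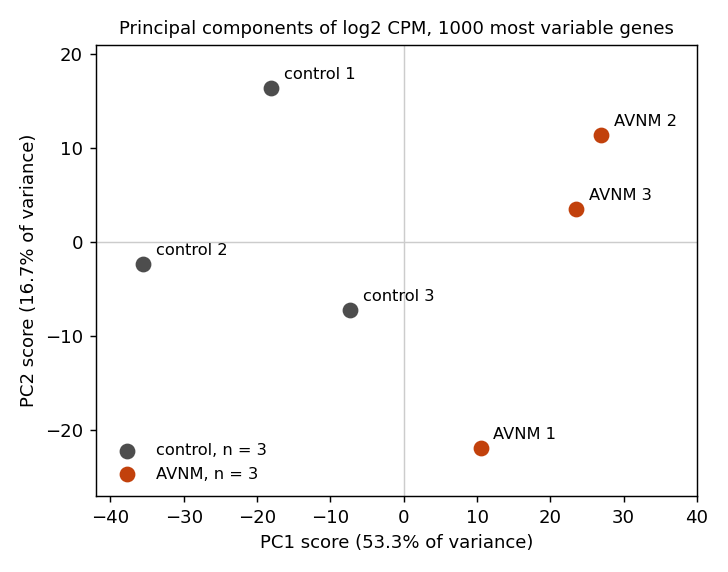
First and second principal components of log2 CPM of the 1000 most variable genes, one point per library, with the share of variance of each component on its axis. The 3 control libraries lie at negative values of the first component, from -35.5 to -7.33, and the 3 AVNM libraries at positive values, from 10.5 to 26.9.

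In the AVNM ileum, 50 of 82 nuclear genes of mitochondrial respiration, 11 of 19 of fatty acid oxidation and 5 of 9 of the adult-type enterocyte were higher, and 12 of 14 of B cells and 6 of 14 of the suckling enterocyte were lower. These 5 lists were called by camera with a preset correlation and by fry, 2 tests of gene lists, but not by camera with an estimated correlation. Whether the pieces came from the same position along the intestine in both groups is not known. A difference in position and an effect of treatment can therefore not be told apart, for these 5 lists or the others below. Of the 17587 genes tested, 1470 (8.36%) changed, of which 782 rose and 688 fell, and 287 changed at least 2-fold, 154 up and 133 down. At an unadjusted p under 0.05 the count was 3993. In 4805 genes (27.3%) every AVNM library lay on one side of every control library, where chance gives 10%. Every gene given here as having risen or fallen is among them. Of 51 gene lists, the camera test with a preset correlation called 16, 10 of them higher and 6 lower in AVNM. With an estimated correlation it called 0 (smallest adjusted p = 0.478). The fry test, which asks whether a list's genes move on balance one way, called 9, of which 8 were shared. It did not call the distal small intestine, tuft cell, carbohydrate handling, fat absorption, fibroblast and matrix, replication histone, ribosomal protein and mitochondrially encoded lists, which camera called. The count of genes depends on single libraries: it was 599 without control 1, 669 without control 2, 2355 without control 3, 1683 without AVNM 1, 614 without AVNM 2 and 667 without AVNM 3. The count at 2-fold was 133, 137, 610, 360, 155 and 169 in the same order. Without both controls that hold Xist, a choice made after seeing the data, the counts were 262 and 74. That setting leaves 1 control. In it the log2 fold changes of the genes called with all 6 libraries had a median ratio of 0.766 to their values in the comparison. Counts per list in that setting are given further below.

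**Figure D2:**
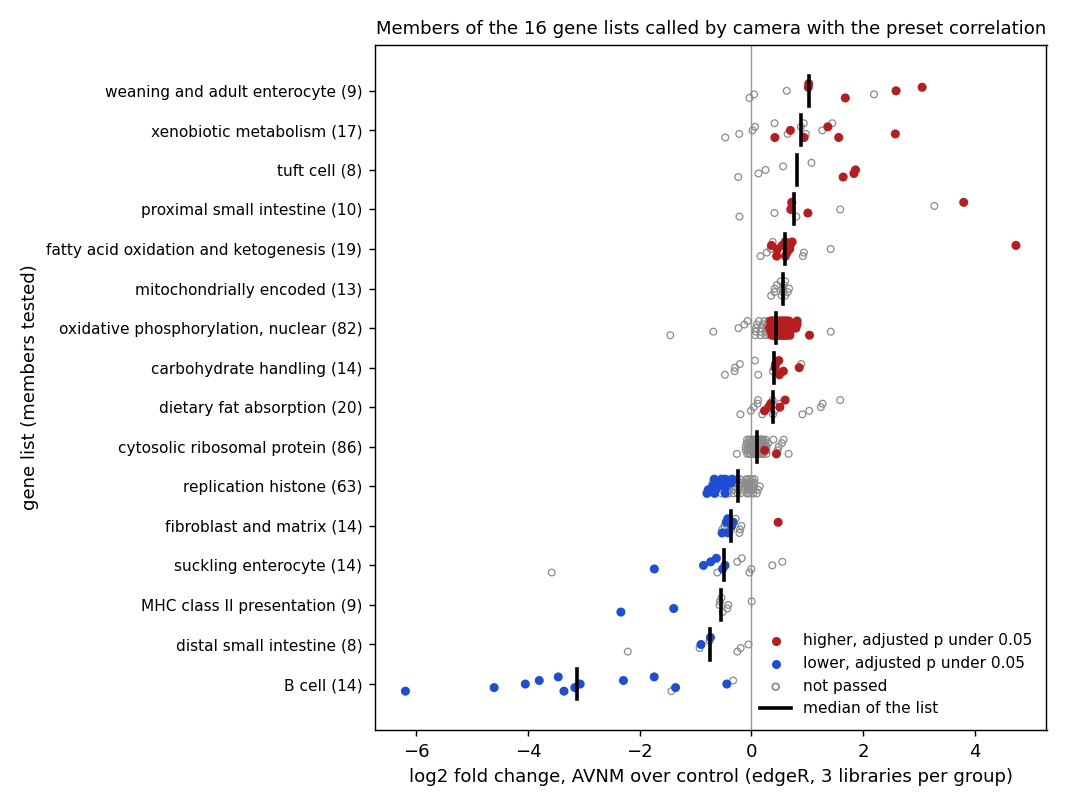
Log2 fold change, AVNM over control, of every tested member of the 16 lists called by the camera test with a preset correlation, one point per gene, with a bar at the median of each list. Filled points passed the edgeR test at an adjusted p under 0.05; the medians run from -3.11 for B cell genes to 1.03 for genes of the weaning and adult enterocyte.

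Some enzymes that the enterocyte normally gains around weaning were higher in AVNM, and some lysosomal and endocytic genes of the suckling enterocyte were lower. Treh (ENSMUSG00000032098.14), which splits the sugar trehalose, rose from 12.9 ± 5.64 CPM to 77.2 ± 8.05 CPM (mean ± SD, n = 3 each; log2 fold change ± SE 2.59 ± 0.31, adjusted p = 0.00907). Arg2, the mitochondrial arginase, rose from 4.28 ± 3.35 CPM to 35.6 ± 1.93 CPM (log2 fold change 3.06 ± 0.50, adjusted p = 0.0301). Of 9 genes of the weaning and adult enterocyte 5 rose, 0 fell and 4 did not pass, with 6 higher adjusted over the list alone. The weaning and adult enterocyte list had a camera adjusted p = 3.23e-06, and adjusted p = 0.478 with an estimated correlation. Others that rose were the fructose transporter Slc2a5 (1.68 ± 0.19) and the fructose kinase Khk (1.03 ± 0.12). Sis, the sucrase-isomaltase of the brush border, stood at 159 ± 105 CPM in control, with 281 CPM in control 3, and at 727 ± 74.5 CPM in AVNM, and did not pass (log2 fold change 2.19 ± 0.54, adjusted p = 0.103). Without control 3 the adjusted p of Sis was 5.96e-11 (5.96e-11 to 0.274 over its alternatives). Lgmn (ENSMUSG00000021190.15), a lysosomal protease, fell from 1749 ± 243 CPM to 524 ± 59.1 CPM (log2 fold change -1.74 ± 0.12, adjusted p = 5.68e-06). Of 14 genes of the suckling enterocyte 6 fell and 8 did not pass, with 1 higher and 9 lower adjusted over the list alone. The suckling enterocyte list had a camera adjusted p = 0.000390, and adjusted p = 0.478 with an estimated correlation. Beside Lgmn, these included the galactosidase Glb1 (-0.63 ± 0.08), the sialidase Neu1 (-0.73 ± 0.13) and Amn (-0.86 ± 0.14), a partner of the uptake receptor cubilin. Other markers of the suckling state did not pass: lactase, Lct (0.55 ± 0.16, adjusted p = 0.0678), the argininosuccinate synthase Ass1 (-0.00014 ± 0.09, adjusted p = 0.999) and the transcription factor Prdm1 (-0.17 ± 0.07, adjusted p = 0.178). Treh had an adjusted p of 0.0761 without control 1, with a range of 1.89e-10 to 0.0761 over its alternatives. Arg2 had an adjusted p of 0.133 without control 1, 0.0702 without AVNM 1, 0.1002 without AVNM 2 and 0.107 without AVNM 3, with a range of 1.78e-09 to 0.133 over its alternatives. Neu1 had an adjusted p of 0.0509 without AVNM 3, with a range of 2.78e-15 to 0.128 over its alternatives. The count of adult genes that rose was 3 without control 1.

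**Figure D3:**
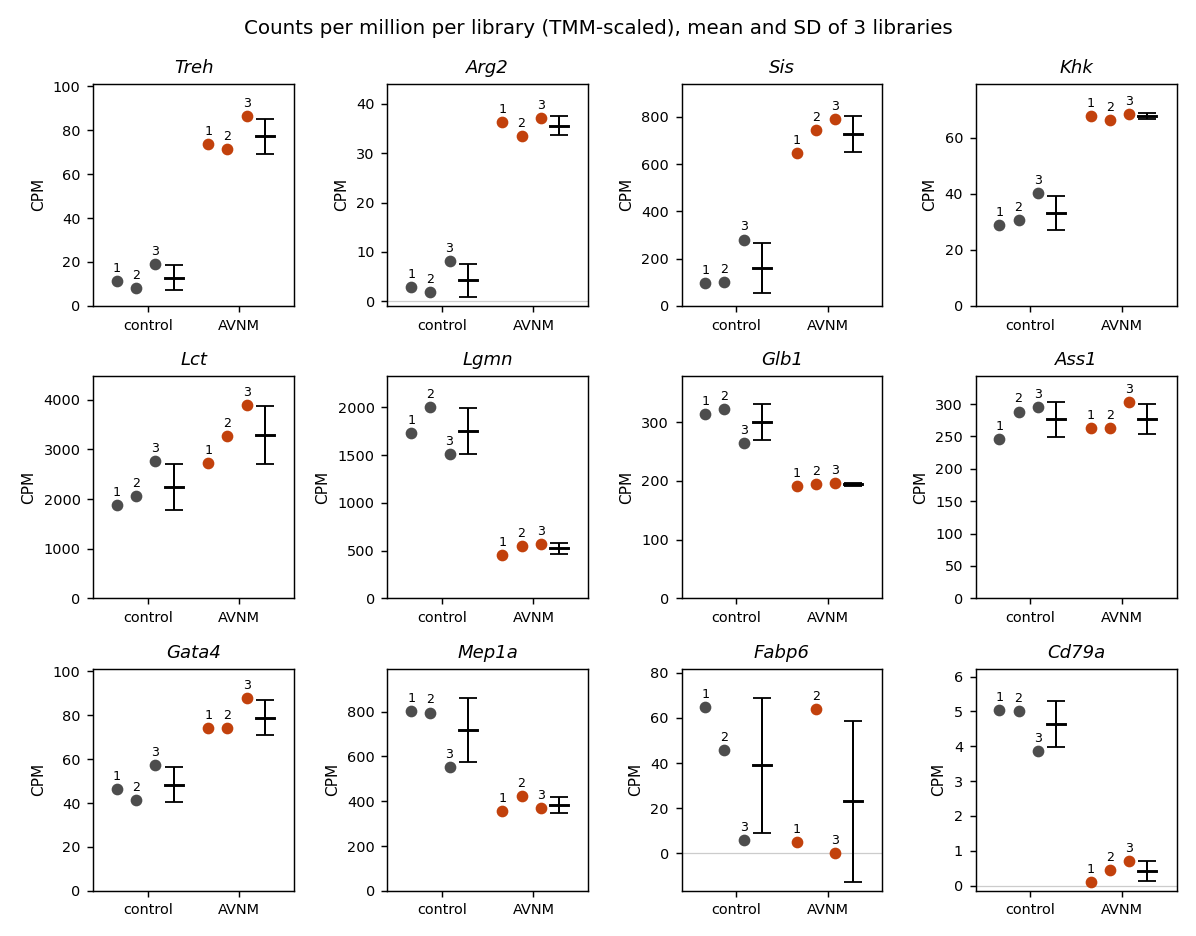
CPM of 12 genes in each library on linear axes that include 0, with dots numbered by replicate and bars for the mean ± SD of 3 libraries per group. Treh, Arg2, Khk, Gata4, Lgmn, Glb1, Mep1a and Cd79a passed the test; Sis, Lct, Ass1 and Fabp6 did not, and Fabp6 ranged from 0.155 to 64.9 CPM without a split by group.

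Some markers of the upper small intestine were higher in AVNM and some of the lower small intestine were lower. Of 10 proximal markers 4 rose and 6 did not pass, with 6 higher adjusted over the list alone. The proximal small intestine list had a camera adjusted p = 1.65e-05, and adjusted p = 0.478 with an estimated correlation. The markers that rose were Gata4, a transcription factor of the upper intestine (log2 fold change 0.71 ± 0.12, adjusted p = 0.00272), the creatine kinase Ckmt1 (0.72 ± 0.12, adjusted p = 0.00260), the glutathione transferase Gstm6 (1.01 ± 0.26, adjusted p = 0.0273) and the alcohol dehydrogenase Adh6a. Adh6a rose from 4.66 ± 3.22 to 64.9 ± 14.8 CPM (3.80 ± 0.50, adjusted p = 0.0211). Onecut2, another proximal marker, did not pass but stood at 19.7, 3.45 and 34.8 CPM in controls and 194, 172 and 189 CPM in AVNM. Of the 10 markers 9 had a positive log2 fold change and 1 a negative one. Of 8 distal markers 2 fell and 6 did not pass, with 2 lower adjusted over the list alone. The distal small intestine list had a camera adjusted p = 0.00853, and adjusted p = 0.542 with an estimated correlation. The markers that fell were the bile acid exporter subunit Slc51a (-0.73 ± 0.11, adjusted p = 0.00259) and the brush border protease Mep1a (-0.90 ± 0.14, adjusted p = 0.00356). Fabp6, the ileal bile acid-binding protein, stood at 64.9, 45.9 and 6.08 CPM in controls and 4.98, 64.0 and 0.155 CPM in AVNM and did not pass (-0.75 ± 1.69, adjusted p = 0.849). Nor did the bile acid importer Slc10a2 (-0.93 ± 1.00, adjusted p = 0.658) or the hormone Fgf15 (-2.21 ± 0.85, adjusted p = 0.239). Of 9 genes of bile acid handling 1 rose, the exporter Abcc3 (0.77 ± 0.14, adjusted p = 0.00354), and 2 fell, Slc51a and the exporter Abcc2 (-0.79 ± 0.11, adjusted p = 0.000830), with 1 higher and 3 lower adjusted over the list alone; this list was not called. The bile acid and FXR list had a camera adjusted p = 0.140, and adjusted p = 0.547 with an estimated correlation. Among 6 markers of caecum and colon 2 rose, the water channel Aqp8 (2.25 ± 0.43, adjusted p = 0.00976) and the sugar phosphate exchanger Slc37a2 (0.87 ± 0.23, adjusted p = 0.0313), with 3 higher and 1 lower adjusted over the list alone. The caecum and colon list had a camera adjusted p = 0.260, and adjusted p = 0.728 with an estimated correlation. Gstm6 had an adjusted p of 0.0919 without control 1, 0.0916 without control 2, 0.0857 without AVNM 2 and 0.101 without AVNM 3, with a range of 0.0187 to 0.399 over its alternatives. Adh6a had an adjusted p of 0.118 without control 1, 0.0601 without AVNM 2 and 0.0815 without AVNM 3, with a range of 4.83e-09 to 0.118 over its alternatives. Slc37a2 had an adjusted p of 0.129 without control 1, 0.141 without control 2, 0.0561 without AVNM 1, 0.0858 without AVNM 2 and 0.104 without AVNM 3, with a range of 0.00194 to 0.892 over its alternatives. The count of proximal markers that rose was 2 without control 1, AVNM 2 or AVNM 3, and that of caecum and colon markers 1 without control 1, control 2, AVNM 1, AVNM 2 or AVNM 3. The distal list's camera adjusted p was 0.0506 without AVNM 1 and 0.0571 without both controls that hold Xist, and its fry adjusted p was 0.0738.

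Many nuclear genes of mitochondrial respiration and of fatty acid oxidation rose. Of 82 nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase, 50 rose, 0 fell and 32 did not pass, with 64 higher and 1 lower adjusted over the list alone. The oxidative phosphorylation list had a camera adjusted p = 8.32e-25, and adjusted p = 0.478 with an estimated correlation. Examples are Atp5f1 of the ATP synthase (log2 fold change 0.69 ± 0.09, adjusted p = 0.000332), Uqcrfs1 of complex III (0.66 ± 0.08, adjusted p = 0.000240) and Cox6a1 of complex IV (0.69 ± 0.09, adjusted p = 0.000332). All 13 mitochondrially encoded genes had a positive log2 fold change, with a median of 0.56, but 0 passed alone (0 adjusted over the list alone). Among them, mt-Co1 had a log2 fold change of 0.52 ± 0.17, adjusted p = 0.0730. The mitochondrially encoded list had a camera adjusted p = 5.51e-05, and adjusted p = 0.593 with an estimated correlation. Mitochondrial genes held 4.22 ± 1.05% of counts in control and 5.79 ± 0.450% in AVNM (mean ± SD, n = 3 each). Of 19 genes of fatty acid oxidation and ketogenesis 11 rose and 8 did not pass, with 18 higher adjusted over the list alone. The fatty acid oxidation and ketogenesis list had a camera adjusted p = 1.18e-11, and adjusted p = 0.478 with an estimated correlation. The oxidation enzymes Acadvl (0.68 ± 0.09, adjusted p = 0.000332), Hadhb (0.61 ± 0.09, adjusted p = 0.00116) and Ehhadh (0.64 ± 0.09, adjusted p = 0.000563) rose. Cyp4a10, a fatty acid hydroxylase, had 0, 0 and 11 counts in the controls and 116, 58 and 131 in AVNM (4.73 ± 0.92, adjusted p = 0.0339). Of 14 genes of carbohydrate handling 6 rose and 8 did not pass, with 7 higher adjusted over the list alone. They included the glycolytic enzymes Eno1 (0.86 ± 0.09), Pkm (0.50 ± 0.07) and Ldha (0.49 ± 0.09). The carbohydrate handling list had a camera adjusted p = 0.0127, and adjusted p = 0.547 with an estimated correlation. Of 20 genes of dietary fat absorption 5 rose and 15 did not pass, with 9 higher adjusted over the list alone. Rising genes here were Mogat2 (0.60 ± 0.10), which re-forms diglycerides in the enterocyte, and the sterol exporter Abcg5 (0.35 ± 0.07). The dietary fat absorption list had a camera adjusted p = 7.10e-06, and adjusted p = 0.547 with an estimated correlation. The count that rose was 6 without control 3 for mitochondrially encoded genes and 7 without control 1 or AVNM 3 for fatty acid oxidation. For carbohydrate handling it was 3 without control 1 or AVNM 3, and for fat absorption 2 without control 1, AVNM 2 or AVNM 3 and 9 without control 3. Of the mitochondrially encoded genes 4 rose with DESeq2, with no filter or with the replicate number as a block. That list's camera adjusted p was 0.0587 without both controls that hold Xist. Cyp4a10 had an adjusted p of 0.0893 without control 1, 0.0547 without control 2, 0.0601 without AVNM 1 and 0.111 without AVNM 3, with a range of 1.11e-08 to 0.111 over its alternatives.

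Some genes that process foreign compounds rose. Of 17 genes of xenobiotic metabolism 6 rose and 11 did not pass, with 10 higher and 2 lower adjusted over the list alone. The xenobiotic metabolism list had a camera adjusted p = 1.56e-05, and adjusted p = 0.478 with an estimated correlation. Those that rose included the cytochrome Cyp3a13, at 179.5 ± 22.8 CPM in control and 345 ± 16.9 CPM in AVNM (log2 fold change 0.94 ± 0.09, adjusted p = 7.88e-05), the glutathione transferase Gsta1 (1.37 ± 0.28, adjusted p = 0.00765) and the carboxylesterase Ces2c (2.58 ± 0.43, adjusted p = 0.0368). Genes of the NRF2 pathway and glutathione went both ways: of 14, 3 rose and 3 fell, with 6 higher and 4 lower adjusted over the list alone. The NRF2 and glutathione list had a camera adjusted p = 0.958, and adjusted p = 0.979 with an estimated correlation. Gclc, the rate-limiting enzyme of glutathione synthesis, fell from 70.6 ± 11.6 to 31.0 ± 2.03 CPM (-1.19 ± 0.12, adjusted p = 7.88e-05) and the peroxide-repair enzyme Srxn1 (-0.48 ± 0.08) fell, while the peroxiredoxin Prdx1 (0.49 ± 0.09) rose. Of 14 genes of amino acid and peptide transport 2 rose and 2 fell, with 3 higher and 3 lower adjusted over the list alone. The proline transporter Slc6a20a rose (0.90 ± 0.08, adjusted p = 5.67e-05) and the peptidase Enpep fell (-0.53 ± 0.09, adjusted p = 0.00326). The amino acid and peptide transport list had a camera adjusted p = 0.795, and adjusted p = 0.908 with an estimated correlation. In the urea cycle, arginine and proline list 1 of 12 genes rose, Otc (0.46 ± 0.09, adjusted p = 0.00773), and 1 fell, Asl (-0.65 ± 0.13, adjusted p = 0.00716), with 2 higher and 1 lower adjusted over the list alone. The urea cycle, arginine and proline list had a camera adjusted p = 0.743, and adjusted p = 0.827 with an estimated correlation. None of the 22 genes of cholesterol synthesis passed, and the list held 0 adjusted over the list alone. The cholesterol synthesis list had a camera adjusted p = 0.743, and adjusted p = 0.917 with an estimated correlation. Ces2c had an adjusted p of 0.168 without control 1, 0.0803 without AVNM 1, 0.119 without AVNM 2 and 0.1205 without AVNM 3, with a range of 1.78e-09 to 0.168 over its alternatives. Otc had an adjusted p of 0.0566 without control 1, 0.0538 without AVNM 2 and 0.0557 without AVNM 3, with a range of 5.59e-06 to 0.483 over its alternatives. The count of xenobiotic genes that rose was 2 without control 1, AVNM 2 or AVNM 3, and that of NRF2 genes 1 without control 2 or AVNM 2. For amino acid and peptide transport, the count that rose was 1 without AVNM 3 and the count that fell 1 without control 1, control 2 or AVNM 3. For the urea cycle list, the count that rose was 0 without control 1, AVNM 2 or AVNM 3 and 3 without AVNM 1.

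With all 6 libraries, B cell genes had the lowest median log2 fold change of the 51 lists. Without AVNM 1 the pancreatic acinar list was lower, at -4.04 against -2.93 for B cell genes. Of 14 B cell genes 12 fell and 2 did not pass, with 13 lower adjusted over the list alone and a median log2 fold change of -3.11. The B cell list had a camera adjusted p = 2.20e-13, and adjusted p = 0.478 with an estimated correlation. Cd79a (ENSMUSG00000003379.8), the signalling chain of the B cell receptor, fell from 4.64 ± 0.663 to 0.417 ± 0.295 CPM (log2 fold change -3.35 ± 0.45, adjusted p = 0.000551), and its partner Cd79b fell as well (-2.29 ± 0.37, adjusted p = 0.00189). The B cell transcription factor Pax5 (-3.46 ± 0.52, adjusted p = 0.00108), the surface marker Ms4a1 (-4.05 ± 0.74, adjusted p = 0.0158) and the complement receptor Cr2 (-3.16 ± 0.71, adjusted p = 0.0239) fell. So did the immunoglobulin segments Ighd (-3.80 ± 0.50, adjusted p = 0.000493), Ighm (-1.74 ± 0.19, adjusted p = 0.000169) and Igkc (-2.10 ± 0.31, adjusted p = 0.00106), whose values are uncertain since family members share sequence. Genes matched as immunoglobulin by the start of their symbol held 0.00585%, 0.00827% and 0.00591% of counts in the controls and 0.00269%, 0.00185% and 0.00189% in AVNM. That match also takes in the symbol Ighmbp2, which is not an immunoglobulin segment. Of 5 plasma cell genes 1 fell, Igkc, with 1 lower adjusted over the list alone. Igha (-1.12 ± 0.49, adjusted p = 0.189, uncertain) and Jchain (-0.47 ± 0.53, adjusted p = 0.657) did not pass. The plasma cell list had a camera adjusted p = 0.103, and adjusted p = 0.547 with an estimated correlation. Of 11 genes of Peyer's patches and follicles 2 fell, the chemokine Cxcl13 (-2.48 ± 0.47, adjusted p = 0.00626) and its receptor Cxcr5 (-3.49 ± 0.74, adjusted p = 0.0104), with 1 higher and 4 lower adjusted over the list alone. The Peyer's patch and follicle list had a camera adjusted p = 0.0530, and adjusted p = 0.547 with an estimated correlation. Camera called it without control 2, AVNM 2 or AVNM 3, with RLE factors and with no filter on low counts, and also with Xist or Fabp6 as a covariate and after the GC and length correction. Of 9 genes of MHC class II presentation 2 fell, H2-Ob (-2.34 ± 0.35, adjusted p = 0.00112) and H2-DMb2 (-1.39 ± 0.36, adjusted p = 0.0301), both uncertain, with 8 lower adjusted over the list alone. H2-Ab1 did not pass (-0.41 ± 0.14, adjusted p = 0.0973, uncertain). The MHC class II presentation list had a camera adjusted p = 0.000124, and adjusted p = 0.478 with an estimated correlation. H2-Ob is known from B cells. Of 5 T cell genes 0 passed, with 1 lower adjusted over the list alone, and Cd3e was below the depth needed for the test, with 8, 25 and 12 counts in the controls and 1, 4 and 4 in AVNM. The T cell list had a camera adjusted p = 0.0599, and adjusted p = 0.478 with an estimated correlation. All 5 had a negative log2 fold change, with a median of -0.84, and fry called the list lower (adjusted p = 0.0436). Camera called it without control 1, control 2, AVNM 1, AVNM 2 or AVNM 3. Of 14 macrophage and monocyte genes 1 fell, Csf1r (-0.42 ± 0.10, adjusted p = 0.0262), with 1 lower adjusted over the list alone. The macrophage and monocyte list had a camera adjusted p = 0.216, and adjusted p = 0.728 with an estimated correlation. Ms4a1 had an adjusted p of 0.0534 without control 1 and 0.0504 without control 2, with a range of 8.51e-20 to 0.163 over its alternatives. Cr2 had an adjusted p of 0.0793 without control 1, 0.0775 without control 2 and 0.0785 without AVNM 1, with a range of 2.00e-09 to 0.347 over its alternatives. Cxcr5 had an adjusted p of 0.0623 without control 1 and 0.0519 without AVNM 2, with a range of 8.69e-06 to 0.408 over its alternatives. H2-DMb2 had an adjusted p of 0.168 without control 1, 0.0720 without control 2, 0.118 without AVNM 2 and 0.0812 without AVNM 3, with a range of 0.00478 to 0.688 over its alternatives. Csf1r had an adjusted p of 0.0964 without control 1, 0.114 without control 2 and 0.0848 without AVNM 2, with a range of 3.79e-05 to 0.366 over its alternatives. The count of B cell genes that fell was 5 without both controls that hold Xist. For MHC class II genes it was 1 without control 1, control 2 or AVNM 2 and 4 without AVNM 3, and for follicle genes 1 without control 1 or AVNM 2. For macrophage genes it was 0 without control 1, control 2 or AVNM 2 and 3 without AVNM 3.

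**Figure D4:**
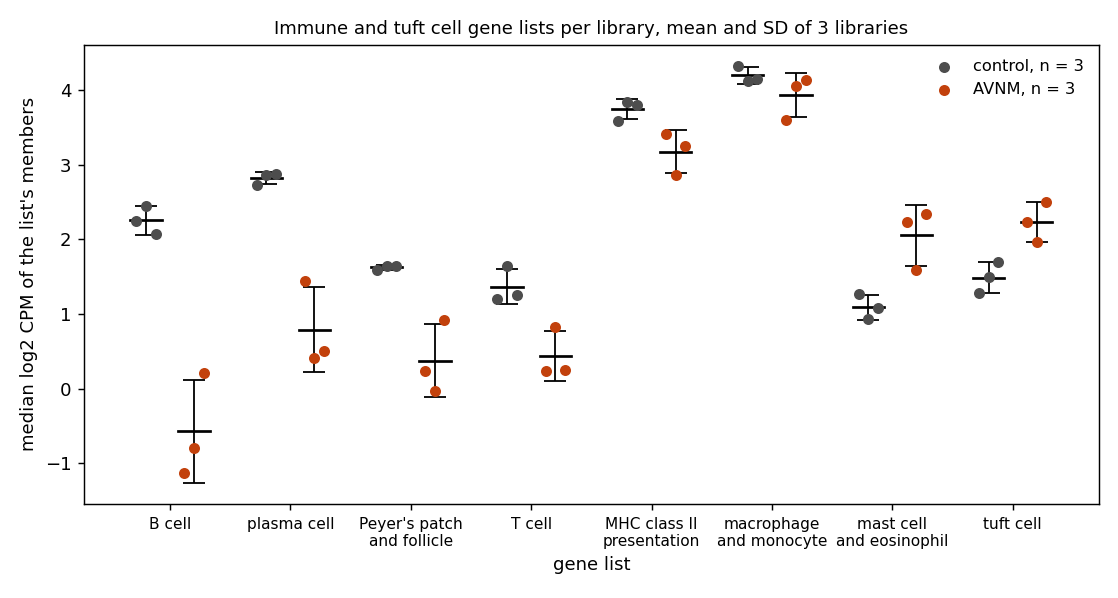
Median log2 CPM over the tested members of 8 cell type and presentation lists, one dot per library, with bars for the mean ± SD of 3 libraries per group. The B cell median was 2.26 ± 0.19 in control and -0.57 ± 0.69 in AVNM, with no overlap of the groups; an exact two-sided permutation test of 3 against 3 cannot give a p under 0.1.

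Genes of the epithelial response to microbes moved in both directions. Of 10 such genes 1 rose and 2 fell, with 1 higher and 2 lower adjusted over the list alone. The microbiota-responsive epithelium list had a camera adjusted p = 0.258, and adjusted p = 0.547 with an estimated correlation. Pigr, the receptor that carries antibodies into the gut lumen, rose from 321 ± 24.8 to 579 ± 32.1 CPM (log2 fold change 0.85 ± 0.09, adjusted p = 7.88e-05), while the barrier protein Sprr2a1 (-0.59 ± 0.10, adjusted p = 0.00202, uncertain) and the oxidase Duox2 (-1.07 ± 0.31, adjusted p = 0.0488) fell. The antimicrobial lectins Reg3b (-0.84 ± 0.26, adjusted p = 0.135) and Reg3g (-0.32 ± 0.25, adjusted p = 0.498), the fucosyltransferase Fut2 (-0.46 ± 0.44, adjusted p = 0.581) and the nitric oxide synthase Nos2 (-0.58 ± 0.42, adjusted p = 0.445) did not pass. Saa1 had 12, 11 and 7 counts in the controls and 2, 0 and 3 in AVNM, and Retnlb 0, 9 and 1 against 3, 0 and 0, too few for the test. Of 14 Paneth cell genes 1 fell, the defensin Defa22 (-0.50 ± 0.09, adjusted p = 0.00287, uncertain), with 1 lower adjusted over the list alone. Lyz1 (0.13 ± 0.12, adjusted p = 0.572) and Ang4 (0.58 ± 0.32, adjusted p = 0.362) did not pass. The Paneth cell list had a camera adjusted p = 0.868, and adjusted p = 0.954 with an estimated correlation. Of 12 goblet cell genes 1 fell, Agr2 (-0.32 ± 0.08, adjusted p = 0.0256), with 1 higher and 4 lower adjusted over the list alone, and the mucin Muc2 did not pass (-0.39 ± 0.12, adjusted p = 0.0560). The goblet cell list had a camera adjusted p = 0.0990, and adjusted p = 0.728 with an estimated correlation. Of 8 tuft cell genes 3 rose, with 5 higher and 1 lower adjusted over the list alone. These included the ion channel Trpm5 (1.83 ± 0.39, adjusted p = 0.0103) and the leukotriene synthase Ltc4s (1.64 ± 0.37, adjusted p = 0.0135). The tuft cell list had a camera adjusted p = 0.00372, and adjusted p = 0.478 with an estimated correlation. Among 5 genes of mast cells and eosinophils 2 rose, with 2 higher adjusted over the list alone, both known from eosinophils: the chemokine receptor Ccr3 (0.99 ± 0.20, adjusted p = 0.00622) and Siglecf (1.15 ± 0.33, adjusted p = 0.0456). The mast cell and eosinophil list had a camera adjusted p = 0.137, and adjusted p = 0.547 with an estimated correlation. Of 14 enteroendocrine genes 1 rose and 4 fell, with 2 higher and 4 lower adjusted over the list alone. The hormones Nts (-0.89 ± 0.14, adjusted p = 0.00292) and Pyy (-1.47 ± 0.26, adjusted p = 0.00316) fell. The enteroendocrine cell list had a camera adjusted p = 0.756, and adjusted p = 0.827 with an estimated correlation. Duox2 had an adjusted p of 0.0830 without control 1, 0.223 without control 2, 0.0654 without control 3, 0.0970 without AVNM 1, 0.0860 without AVNM 2 and 0.129 without AVNM 3, with a range of 0.0244 to 0.560 over its alternatives. Agr2 had an adjusted p of 0.103 without control 1, 0.0916 without control 2, 0.0617 without AVNM 1 and 0.0773 without AVNM 3, with a range of 0.00188 to 0.325 over its alternatives. Trpm5 had an adjusted p of 0.0508 without control 2 and 0.0698 without AVNM 3, with a range of 4.15e-05 to 0.0736 over its alternatives. Ltc4s had an adjusted p of 0.0530 without control 1, 0.0603 without control 2 and 0.0789 without AVNM 2, with a range of 0.00149 to 0.364 over its alternatives. Siglecf had an adjusted p of 0.119 without control 1, 0.171 without control 2, 0.0824 without AVNM 1 and 0.172 without AVNM 3, with a range of 0.0219 to 0.672 over its alternatives. The count of tuft cell genes that rose was 1 without control 1, AVNM 2 or AVNM 3 and 0 without control 2. For enteroendocrine genes, the count that fell was 2 without control 1, control 2 or AVNM 3. The count that fell was 1 without control 1, control 2, control 3, AVNM 1, AVNM 2 or AVNM 3 for microbe-response genes, 0 without control 1, control 2 or AVNM 1 and 4 without control 3 for goblet cell genes and 2 without control 1 or AVNM 1 for Paneth cell genes. The count of mast cell and eosinophil genes that rose was 1 without control 1, control 2, AVNM 1 or AVNM 3.

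Some histone and matrix genes fell. Of 63 replication histone genes 15 fell and 48 did not pass, with 24 lower adjusted over the list alone. This list, of non-polyadenylated histone genes, was fixed as a check and not as a pathway or cell type. What lowered these genes was not tested. Their values are uncertain since family members share sequence, so the genes that fell may not be separate measurements. Examples are Hist2h3c2 (log2 fold change -0.80 ± 0.13, adjusted p = 0.00201) and Hist1h1c (-0.47 ± 0.07, adjusted p = 0.00127). The replication histone list had a camera adjusted p = 9.46e-07, and adjusted p = 0.542 with an estimated correlation. Of 20 proliferation genes 1 rose, Pcna (0.42 ± 0.10, adjusted p = 0.0226), with 1 higher adjusted over the list alone, and Mki67 did not pass (0.14 ± 0.09, adjusted p = 0.386), nor did the stem cell marker Lgr5 (-0.24 ± 0.11, adjusted p = 0.203), while the stem cell gene Axin2 fell (-0.36 ± 0.08, adjusted p = 0.0122). The proliferation list had a camera adjusted p = 0.216, and adjusted p = 0.811 with an estimated correlation. Of 14 fibroblast and matrix genes 6 fell and 1 rose, with 1 higher and 12 lower adjusted over the list alone. The collagens Col1a1 (-0.45 ± 0.09, adjusted p = 0.00852) and Col6a1 (-0.41 ± 0.08, adjusted p = 0.00619) fell. The fibroblast and matrix list had a camera adjusted p = 0.000292, and adjusted p = 0.547 with an estimated correlation. Of 86 cytosolic ribosomal protein genes 2 rose, Rpl30 (0.24 ± 0.07, adjusted p = 0.0444) and Rpl39 (0.45 ± 0.12, adjusted p = 0.0479), with 0 adjusted over the list alone. After a correction for GC content and length, chosen after seeing the data, the list's camera adjusted p was 0.0925. The cytosolic ribosomal protein list had a camera adjusted p = 2.64e-05, and adjusted p = 0.547 with an estimated correlation. Of 17 genes of tight junctions and adhesion 2 rose and 1 fell, with 3 higher and 1 lower adjusted over the list alone: the claudin Cldn15 rose (0.72 ± 0.10, adjusted p = 0.000596) and Cldn4 fell (-0.60 ± 0.10, adjusted p = 0.00201). The tight junction and adhesion list had a camera adjusted p = 0.710, and adjusted p = 0.811 with an estimated correlation. The neuronal marker Elavl4 (-0.52 ± 0.29, adjusted p = 0.314) and the clock gene Nr1d1 (0.19 ± 0.24, adjusted p = 0.706) did not pass, but Ret of the same neuron list (-0.48 ± 0.11, adjusted p = 0.0173) and the clock genes Cry1 (-0.44 ± 0.11, adjusted p = 0.0275) and Cry2 (-0.62 ± 0.15, adjusted p = 0.0307) fell. Axin2 had an adjusted p of 0.0651 without control 2 and 0.0668 without AVNM 3, with a range of 0.00160 to 0.276 over its alternatives. Ret had an adjusted p of 0.103 without control 1, 0.0840 without control 2 and 0.0632 without AVNM 2, with a range of 4.82e-06 to 0.698 over its alternatives. Cry1 had an adjusted p of 0.160 without control 1, 0.0678 without AVNM 1, 0.0775 without AVNM 2 and 0.0782 without AVNM 3, with a range of 0.0101 to 0.334 over its alternatives. Cry2 had an adjusted p of 0.103 without control 1, 0.102 without control 2, 0.0966 without AVNM 2 and 0.138 without AVNM 3, with a range of 1.89e-06 to 0.569 over its alternatives. Pcna had an adjusted p of 0.0919 without control 1, 0.110 without control 2, 0.0931 without AVNM 2 and 0.124 without AVNM 3, with a range of 0.000160 to 0.590 over its alternatives. Col1a1 had an adjusted p of 0.0649 without control 1, 0.0827 without AVNM 2 and 0.0505 without AVNM 3, with a range of 5.86e-06 to 0.475 over its alternatives. Col6a1 had an adjusted p of 0.0583 without control 1 and 0.0512 without AVNM 3, with a range of 4.18e-05 to 0.329 over its alternatives. Rpl30 had an adjusted p of 0.141 without control 1, 0.189 without control 2, 0.190 without AVNM 2 and 0.131 without AVNM 3, with a range of 0.0283 to 0.819 over its alternatives. Rpl39 had an adjusted p of 0.187 without control 1, 0.0905 without control 2, 0.13 without AVNM 1, 0.118 without AVNM 2 and 0.168 without AVNM 3, with a range of 7.02e-06 to 0.883 over its alternatives. The count of histone genes that fell was 3 without control 1, 4 without control 2, 8 without AVNM 1, 5 without AVNM 2 and 9 without AVNM 3. For fibroblast and matrix genes it was 0 without control 1 or AVNM 3, 3 without control 2, 10 without control 3 and 1 without AVNM 2. Ribosomal protein genes that rose numbered 0 without control 1, control 2, AVNM 2 or AVNM 3, 11 without control 3 and 1 without AVNM 1. The count of proliferation genes that rose was 0 without control 1, control 2, AVNM 2 or AVNM 3, and that of junction genes 1 without control 1, control 2 or AVNM 3.

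The largest changes among well-measured genes lay partly outside the lists. Ggt1 (ENSMUSG00000006345.11), which breaks down glutathione at the cell surface, rose from 3.25 ± 2.23 to 63.8 ± 7.996 CPM (log2 fold change 4.29 ± 0.40, adjusted p = 0.00406), and Reg1, a secreted lectin, from 3.48 ± 2.20 to 45.8 ± 8.79 CPM (3.70 ± 0.40, adjusted p = 0.00586). The complement component C8b rose from 0.845 ± 0.809 to 11.7 ± 1.51 CPM (3.83 ± 0.60, adjusted p = 0.0101). The water and glycerol channel Aqp3 (3.11 ± 0.41, adjusted p = 0.000528), the proton channel Otop3 (2.82 ± 0.50, adjusted p = 0.00297) and the lactate transporter Slc5a12 (2.33 ± 0.40, adjusted p = 0.00366) rose. Among the largest falls, the kinase Sgk2 went from 17.2 ± 3.30 to 3.32 ± 1.33 CPM (-2.40 ± 0.28, adjusted p = 0.000357), Bex4 from 15.8 ± 5.31 to 3.82 ± 1.05 CPM (-2.07 ± 0.28, adjusted p = 0.00117) and the fibrinogen chain Fgb from 5.04 ± 2.95 to 0.413 ± 0.399 CPM (-3.62 ± 0.78, adjusted p = 0.0261). C8b had an adjusted p of 0.0530 without AVNM 3, with a range of 7.63e-28 to 0.116 over its alternatives. Fgb had an adjusted p of 0.0614 without control 1, 0.0669 without control 2 and 0.0956 without AVNM 1, with a range of 2.86e-13 to 0.475 over its alternatives. The camera test did not call 35 lists, of which 24 held at least 1 gene that passed and 11 held 0: T cell, cholesterol synthesis, endothelium, glucocorticoid response, immediate early and heat shock, interferon response, mesothelium and adipocyte, neutrophil, red blood cell, sex-linked and smooth muscle genes. Interferon response genes, 25 tested, had a median log2 fold change of -0.16. The interferon response list had a camera adjusted p = 0.230, and adjusted p = 0.827 with an estimated correlation. With the replicate number as a block, 7 of the 12 smooth muscle genes fell and camera called that list and the T cell list. For 9 of the 24 lists no count is given above. Among genes of the circadian clock 2 of 18 fell, and 1 fell of 19 of enteric neurons, 5 of interstitial cells of Cajal, 10 of intestinal stem cells, 15 of pancreatic acini and 16 of the integrated stress and unfolded protein response. In enteric glia 1 of 6 rose, among inflammatory cytokine genes 1 of 9 rose, and in the interleukin 17 and 22 axis 1 of 7 rose and 1 fell. Adjusted over the list alone the counts were the same but for 3 lower in the circadian clock and 3 in the stress response. Their camera adjusted p ran from 0.136 to 0.847, and from 0.728 to 0.917 with an estimated correlation. Without control 2 all these counts were 0 but for 1 in the circadian clock. The median, the mean and the test differed in sign for 7 of the 35: enteric glia, neutrophil, NRF2 and glutathione, Paneth cell, sex-linked, tight junction and adhesion, and urea cycle, arginine and proline.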

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

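The tests with Xist or Fabp6 as a covariate, with protein-coding genes only, with a correction for GC content and length, and without both controls that hold Xist were chosen only after the result was seen. Every gene called in the comparison kept its direction under each alternative in which it was present. From 1470 genes, 287 of them at least 2-fold, the counts moved by over 1.5 times with 1 library left out (599 to 2355, and 133 to 610 at 2-fold), with no filter on low counts, which tests more genes (2333 and 478), and without both controls that hold Xist, which leaves 1 control assumed to vary like the other libraries (262 and 74). They also moved with Xist as a covariate (734 and 162) and with Fabp6 as a covariate (651 and 148); each covariate uses up 1 residual degree of freedom, and any other cause was not tested. At an adjusted p under 0.1, a looser threshold, the gene count was 2256. Without scaling factors, at library size only, the median log2 fold change of all genes shifted from -0.02 to -0.11 and 38.1% of 1603 calls were higher, against 53.2%. With upper-quartile factors 48.0% of 1505 calls were higher. The GC and length correction went the other way, with 62.7% of 1357 calls higher; before it, log2 fold changes across genes had a Spearman correlation of -0.198 with GC content and -0.177 with transcript length. With the replicate number as a block the count was 2030, with 1432 of the 1470 kept; the correlations of deviations between libraries that share a number were -0.05, -0.18 and 0.09, and the pairs share only a number. Of the 16 lists called, fry called 8 and the T cell list besides, 9 in all, and camera with an estimated correlation called 0; fry does not compare a list with other genes, and the estimated correlation differs from the preset by construction.

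Counts of passing genes per list moved as well; those given here differ by over 1.5 times and hold at least 3 genes in either setting. Without both controls that hold Xist, nuclear oxidative phosphorylation went from 50 to 9, fatty acid oxidation from 11 to 4, B cell genes from 12 to 5, suckling enterocyte genes from 6 to 3, carbohydrate handling from 6 to 3, proximal markers from 4 to 2 and enteroendocrine genes that fell from 4 to 1. Histone (15), fibroblast and matrix (6), fat absorption (5), tuft cell (3) and rising NRF2 genes (3) went to 0. With Fabp6 and with Xist as a covariate, in this order, histone genes went to 6 and 4, xenobiotic genes from 6 to 2 and 3, fat absorption to 1 and 2, fibroblast and matrix to 0 and 2, enteroendocrine genes that fell to 2 and 2 and tuft cell genes to 1 and 1; proximal markers went to 2 with Fabp6. Fibroblast and matrix genes went to 2 with the GC and length correction. Counts rose with library size only and with no filter, for example to 23 in both for histone genes and 7 in both for MHC class II genes, from 2. With the replicate block, smooth muscle genes that fell went from 0 to 7, fibroblast and matrix genes to 10, fat absorption to 9, ribosomal protein genes from 2 to 6, mitochondrially encoded genes from 0 to 4, MHC class II genes to 4, and immediate early and macrophage genes to 3 each. With DESeq2, fat absorption went to 9, MHC class II and ribosomal protein genes to 5 each, mitochondrially encoded genes to 4 and goblet cell genes to 3. Camera also called lists that it had not called in the comparison. With 1 library left out these were plasma cell (control 1, AVNM 1), interferon response and endothelium (control 2, AVNM 3), pancreatic acinar (control 1, AVNM 1), smooth muscle (control 3, AVNM 1) and macrophage and monocyte (AVNM 3). So were goblet cell, mast cell and eosinophil, and bile acid and FXR (all AVNM 2), glucocorticoid response (control 1), and enteric neuron, proliferation, and immediate early and heat shock (all AVNM 1). With the replicate block they were smooth muscle and T cell, with no filter T cell, Peyer's patch and follicle, mast cell and eosinophil, and plasma cell.

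Genes that turned sign did not pass in the comparison. Ass1, with a log2 fold change of -0.00014, stood at 0.0115 with RLE factors, 0.0113 with DESeq2, 0.00170 with limma-voom, 0.0101 with limma-trend, 0.00722 without the 4 gene classes, 0.000909 with the replicate block, 0.00817 with Xist, 0.0150 with protein-coding genes only and 0.0390 with the GC and length correction. With 1 library left out it ranged from -0.0712 to 0.0509, Nr1d1 from -0.0128 to 0.316 and Reg3g from -0.521 to 0.0203. Without both controls that hold Xist, Elavl4 stood at 0.23, Fut2 at 0.46, Nos2 at 0.00327, Fabp6 at 1.93 and Slc10a2 at 1.08. Depth limits what can be said of Cd3e, Saa1 and Retnlb, which had too few counts to be tested.

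The 10 splits of the libraries are too few for a share under 0.05. The real split called 1470 genes and the highest other 12, and 287 against 12 at 2-fold, so 1 split, the real one, gave as many in each case; for lists it called 16 and the highest other 20, with 4 splits as large, the real one included. For lists called by fry it was 9 against 1, with the real split alone as large. Every other split mixes AVNM and control libraries in each group, which raises the spread within groups. Few genes called there are therefore likely whatever sets the groups apart.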

Other observations

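The explanations weighed below were tested, and the lists that open this part were written, only after the result was seen; the fixed lists and their camera and fry tests were planned. Of 48 genes of lysosomal enzymes and membrane proteins 30 fell in AVNM and 18 did not pass, with a median log2 fold change of -0.40. Among those that fell were the hexosaminidase Hexa (-0.94 ± 0.10), the protective protein Ctsa (-0.77 ± 0.09) and the mannosidase Man2b2 (-0.85 ± 0.08), all log2 fold changes ± SE over n = 3 against 3. In carbon metabolism 9 of 15 glycolysis genes rose, and 14 of 17 genes of the tricarboxylic acid cycle, among them Mdh2 (0.69 ± 0.09). Among hormone genes Ghrl, of the upper intestine, rose (0.98 ± 0.28, adjusted p = 0.0427), 1 of 4 tested there, and all 3 tested of the lower intestine, Nts, Pyy and Gcg, fell. All these lists hold genes of the fixed lists whose changes had been seen, such as Lgmn, Eno1 and Pyy, so no list test is given. Ghrl had an adjusted p of 0.0697 without control 1, 0.164 without control 2, 0.0795 without control 3, 0.0530 without AVNM 1, 0.122 without AVNM 2 and 0.131 without AVNM 3, with a range of 0.0301 to 0.356 over its alternatives. Gcg had an adjusted p of 0.0997 without control 1, 0.121 without control 2, 0.0885 without AVNM 1 and 0.162 without AVNM 3, with a range of 0.000691 to 0.316 over its alternatives.

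Of 33 enterocyte genes over 3 lists 15 passed, 9 adult and proximal genes that rose in AVNM and 6 suckling genes that fell; with an estimated correlation none of the 3 lists was called. With Fabp6 as a covariate the median ratio of their log2 fold changes was 0.934, and 11 of the 15 still passed. Fabp6 did not split by group, so this cannot decide on an unequal share of terminal ileum. With Xist as a covariate the ratio was 0.953, and 13 of the 15 still passed. That covariate joins controls 1 and 2, which also hold Y-linked RNA, with AVNM 3, so unequal sex is not settled. Without both controls that hold Xist the list median was 0.756 for adult genes, against 1.03, and -0.316 for suckling genes, against -0.494. The calls lost with Fabp6 kept most of their size but had a larger error or fewer degrees of freedom: Arg2 went from 3.06 ± 0.50 to 2.90 ± 0.52, Adh6a from 3.80 ± 0.50 to 3.62 ± 0.52, Gstm6 from 1.01 ± 0.26 to 1.00 ± 0.30 and Gla from -0.52 ± 0.11 to -0.47 ± 0.13, and with Xist Gstm6 (1.06 ± 0.28) and Gla (-0.48 ± 0.13) were lost. A complete switch to the adult enterocyte is argued against by Ass1, Prdm1 and Lct, whose lowest bound (log2 fold change minus 2 SE) was -0.32. This holds only if the pieces came from the same position in both groups, which is not known. Also open are a partial shift of the programme with treatment and pieces taken further from the caecum. Of 10 proximal markers 7 lay higher in every AVNM library, which either could give.

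Of 14 B cell genes 12 fell in AVNM, with a median log2 fold change of -3.11 over the list, which was not called with an estimated correlation. Depth does not account for it, since the mean total count of the AVNM libraries was 1.09 times that of the controls, and an equal loss of immune cells of every kind is argued against by a median log2 fold change of -0.0893 for macrophage and monocyte genes. A loss of T cells beside B cells is not excluded, since the 5 T cell genes had a median of -0.84 and fry called them lower, but 0 of the 5 passed and camera did not call the list (adjusted p = 0.0599, and 0.478 with an estimated correlation). Less lymphoid follicle tissue in the AVNM pieces may be part of the pattern. The 8 follicle genes tested, apart from Cxcr5, Ltb, Spib, Ccr7 and Lta, which were taken as made by B cells, had a median of -0.65. Whether B cells make any of the 8 was not tested. The median of the 8 genes lay between no change and -1.56, a cut derived from the B cell median after the result was seen. The cut is not a minimum that such a loss requires, so the test does not decide. A sampling difference and fewer or smaller follicles after treatment cannot be told apart here, since both lower follicle genes.

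Controls 1 and 2 held Xist beside Y-linked RNA. Reads of X-linked homologs are argued against, since AVNM 3, with Xist, held Y-linked RNA at 1.87% of the level in these controls, and so is carry-over from the AVNM libraries without Xist, since Arg2, Treh and Sis reached at most 0.533 of the level it would bring. RNA from males and females in 1 library may be the source: the 4 Y-linked genes stood at 31.7% to 40.2% of the libraries without Xist in control 1 and 17.3% to 32.2% in control 2, a highest to lowest ratio of up to 1.86. It stays open, because the Y-linked share and the Xist level relative to AVNM 3 add up to 120% in each, where a plain mixture gives about 100%, and because AVNM 3 is the only library with Xist alone. No biological explanation of this pattern was tested.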
